A study of Mus musculus with 24 samples.

How the data were processed

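Hippocampal total RNA of PS19 mice was enriched with oligo(dT) beads and sequenced as 24 libraries, per the labels' protocols. The values used were read counts per gene symbol for 24 libraries, deposited as whole numbers and aligned to GRCm38 per the labels. The aligner, the counting program, the annotation and the strand setting are not given in the sources used here. The deposited counts carried 24058 symbols. Of these, 25 had been turned into dates (0.353% of the counts) and stayed in under that form, and no mitochondrially encoded gene had an entry. The tables held 18 more columns that matched no sample of the series (6 in the hippocampal table and 12 in an in vitro table), and these were not used here.

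Counts were filtered with filterByExpr, which left 16118 genes, and scaled with TMM factors. Expression was fitted with the quasi-likelihood model of edgeR 4.0.16 in R 4.3.3, with all 24 libraries and a mean for each of the 6 groups. P-values were adjusted by Benjamini and Hochberg's method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM with TMM factors, as mean and SD. Trem2 was tested by two-sided exact permutation of log2 CPM, without a prior count, within each sex and prefix. In this test and for list scores the p was 2 times the smaller tail. The smallest possible p was thus 2 divided by the number of groupings. The log2 CPM behind list scores and principal components had a prior count of 2. Gene positions and transcript lengths came from GENCODE M21, which gave a length for 95.3% of the genes tested. The comparisons, the edgeR test, the alternatives and 43 gene lists were set before the data were examined.

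Of the 43 lists, 41 had at least 5 tested genes. They were tested with camera of limma 3.58.1 on voom weights, with its preset correlation of 0.01 between genes. The same lists were tested with the correlation estimated for each list, with fry, and by exact permutation of list scores (the mean centred log2 CPM of a list's genes in a library), where a difference of 2 effects used all combined regroupings within its 2 pairs of groups. "Adjusted over the list alone" means that the p-values of a list's genes were adjusted among themselves. A gene on several lists counts once in each.

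The genes named were chosen by a rule set before the data were examined. In each genotype comparison it took the 10 smallest p-values where fewer than 10 genes passed, leaving out predicted genes, with Trem2, Mapt and Prnp and up to 4 genes with the smallest p of each list called. The text gives up to 2 of those 4 genes for some lists. Genes named behind small counts of other tools were chosen after their values were seen.

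Alternatives were size factors of DESeq2 and upper-quartile factors, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, a robust fit, no filter, fits of the compared groups alone, 1 surrogate variable (sva 3.50.0), an adjusted p under 0.1, pooled Trem2+/+ females, the mean R47H effect over both sexes, a direct contrast of R47H-TREM2 with WT-TREM2, and leaving out each of 24 libraries in turn. EdgeR stayed the main test because it had been set before the data were examined, although DESeq2 called 187 genes in R47H-TREM2 females. Further choices were made after the data were seen: the split of libraries at an Alb of 30 CPM, the 6 doubted libraries (Prl or Omp above 50 CPM, or Adora2a above 30 CPM), a covariate for each library's slope of log2 expression on log2 transcript length, and the exact permutation of list scores. The rule that decided the tests of liver batch, depth and transcript length in the closing section was changed after their results were seen, and both outcomes are given there.

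Depth ran from 13261478 to 23807390 counts per library, and the common biological coefficient of variation was 0.318. The first 2 principal components held 19.4% and 15.5% of the variance. The tests were tried on simulated data with the group sizes, depths and spread of the libraries. For genes set to differ 2 times, edgeR recovered 32.8% in R47H-TREM2 females, 40.3% in WT-TREM2 females, 13.4% in R47H-TREM2 males, 10.4% for the difference of the R47H and WT effects and 7.46% for the difference between the sexes. For genes set to differ 4 times it recovered 87.7%, 80.3%, 75.8%, 67.7% and 54.5%. Among unchanged genes edgeR called 1 to 5 in each comparison and DESeq2 13 to 20. Simulated genes were drawn independently of each other, which favours camera with its preset correlation, and genes set to differ had a mean above 1 CPM. The simulation held no differences shared by many genes of a library, so its rates may not hold for the real libraries. Other groupings of the real LG72 females gave up to 234 calls in edgeR and 1128 in DESeq2. Camera found 3 of 3 raised lists in each comparison except the difference of the R47H and WT effects, where it found 2 and called 1 unchanged list.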

Results

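Bulk RNA sequencing was carried out on hippocampal tissue of PS19 mice, a tauopathy line with a human tau transgene that carries the P301S change. The mice differed at the Trem2 locus, which encodes a lipid-sensing receptor of microglia. They had mouse Trem2 alone (Trem2+/+), 1 human TREM2 allele of the common form (WT-TREM2) or 1 human TREM2 allele with the R47H change that is linked to Alzheimer's disease (R47H-TREM2). The 24 libraries formed 6 groups. Titles starting with LG72 covered 5 R47H-TREM2 females, 3 Trem2+/+ females, 5 R47H-TREM2 males and 2 Trem2+/+ males, and titles starting with LG73 covered 6 WT-TREM2 females and 3 Trem2+/+ females. The labels give no meaning for these prefixes, and R47H-TREM2 and WT-TREM2 never shared one. Total counts ran from 13261478 to 23807390 per library. The 5 R47H-TREM2 females (13261478 to 17442293) were all shallower than their 3 controls (17545680 to 23807390). Each title carries a number of its own within its prefix, but the labels do not say what it numbers, so p-values measure the spread between these libraries. Counts of any 2 libraries of a group differed beyond counting noise (chi-square per degree of freedom at least 11.1).

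Trem2 (chromosome 17, 48346401 to 48354147, GRCm38) was measured first, since the human alleles were placed at this locus. In females of LG72 it stood at 18 ± 8.85 CPM with R47H-TREM2 and 16.5 ± 10.3 without (SD, n = 5 and 3; log2 difference 0.22, two-sided exact permutation p = 0.786 on log2 values). In females of LG73 it stood at 12.4 ± 11.1 with WT-TREM2 and 11.9 ± 4.98 without (SD, n = 6 and 3; log2 difference −0.30, the other way from the means, exact permutation p = 0.762). In males it was 11.5 ± 3.23 with R47H-TREM2 and 24.1 ± 4.60 without (SD, n = 5 and 2, log2 difference −1.10, exact permutation p = 0.0952). With the smaller tail doubled, this was the smallest p these group sizes allow. In both female comparisons the direction of the log2 difference turned when some single library was left out. Whether reads of the human allele could be counted under mouse Trem2 is not given in the sources used here, so the values do not check the genotype labels. Mapt, which encodes tau (chromosome 11, 104231390 to 104332090), and Prnp, the prion protein gene (chromosome 2, 131909928 to 131938429), did not differ past the test. Whether reads of the human tau transgene could be counted under Mapt or Prnp is likewise not given. The log2 fold changes of Mapt and Prnp were 0.06 and −0.15 in R47H-TREM2 females (edgeR adjusted p = 0.904 and 0.781), 0.25 and −0.00 in WT-TREM2 females (0.860 and 0.997), and 0.12 and −0.17 in R47H-TREM2 males (0.917 and 0.897).

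**Figure D1:**
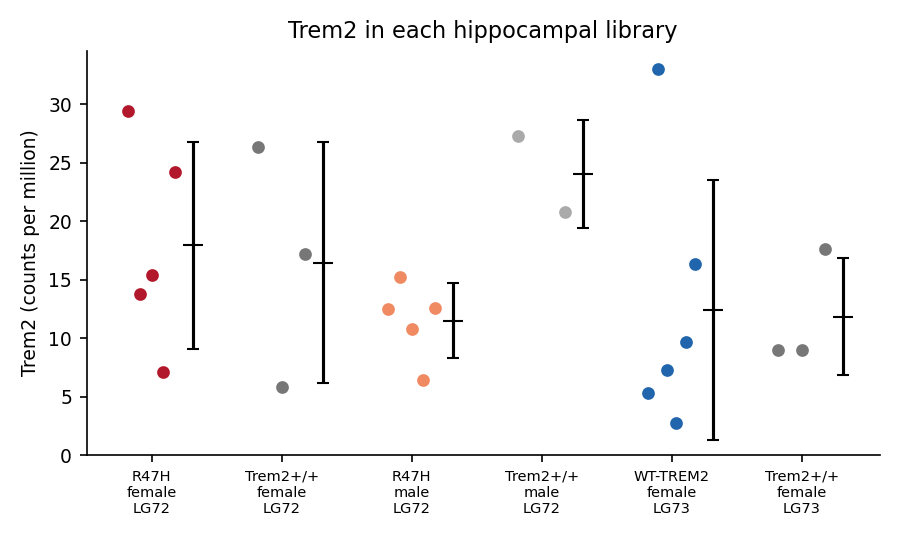
Trem2 in CPM for each library of the 6 groups, with points for libraries and bars for the group mean and SD. The groups overlap in females, and the 2 Trem2+/+ males lie above the 5 R47H-TREM2 males.

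Transcripts of other organs differed between libraries within groups. Alb, the main plasma protein of liver, stood at 57.5 to 224 CPM in 14 libraries and at 1.71 to 15.1 in the other 10. The high libraries numbered 2 of 5 R47H-TREM2 females and 2 of their 3 controls, 4 of 6 WT-TREM2 females and 1 of 3 controls, and 4 of 5 R47H-TREM2 males and 1 of 2 controls. Prl, a pituitary hormone, reached 972 CPM in R47H-TREM2 female 5 of LG72, and Omp, a marker of olfactory sensory neurons, reached 419 in Trem2+/+ female 1 of LG72. Adora2a, a receptor of striatal projection neurons, reached 53.8 in Trem2+/+ female 3 of LG72 and 57.7 and 33.6 in WT-TREM2 females 2 and 5. These 5 libraries and Trem2+/+ female 3 of LG73, with Prl at 58.7, are called the 6 doubted libraries here.

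**Figure D2:**
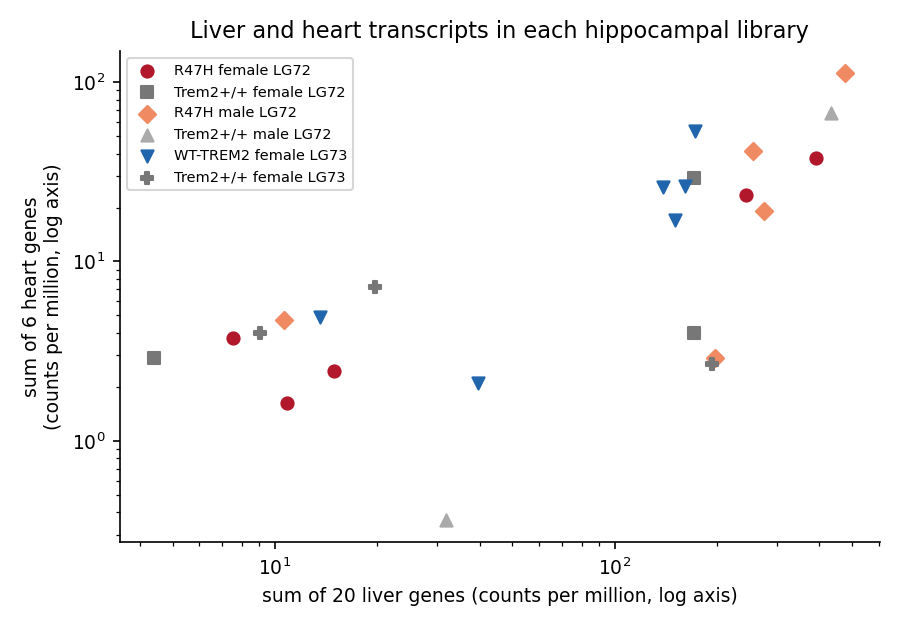
Summed CPM of 20 liver genes and of 6 heart muscle genes in each of the 24 libraries, on logarithmic axes. The 14 libraries with high liver transcripts stand apart from the other 10 at 138.8 to 476.4 against 4.42 to 39.7, and heart transcripts are high in 11 of the 14.

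The first comparison asked how hippocampal expression differed between R47H-TREM2 and Trem2+/+ females of LG72. Gene groups of microglia, reactive astrocytes and interferon signalling were higher in the R47H-TREM2 libraries. Of 26 genes of resting microglia 25 were higher, with a median log2 fold change of 0.88. Aif1, a microglial calcium-binding protein, measured 31.8 ± 20.5 CPM against 8.29 ± 0.916 (SD, n = 5 and 3; log2 fold change 1.93, SE 0.44, edgeR adjusted p = 0.141). Genes raised in microglia near neurodegenerative pathology were higher in 31 of 35 cases (median 0.97), with Ccl6, a chemokine, at 11.4 ± 5.83 against 2.36 ± 1.34 and Cd63, a tetraspanin, at 231 ± 90.9 against 92.3 ± 34.9 (SD, n = 5 and 3). Reactive astrocyte genes were higher in 28 of 29 cases (median 1.36) and interferon-stimulated genes in 33 of 34 (median 1.19). Gbp2, a guanylate-binding protein on both lists, measured 12.1 ± 4.85 against 2.94 ± 1.01 (SD, n = 5 and 3; log2 fold change 2.03, SE 0.53, edgeR adjusted p = 0.173). Genes of signalling downstream of TREM2 were higher in 20 of 21 cases (median 0.75). Among them were the phosphatase genes Ptpn6 at 13 ± 5.87 against 4.31 ± 1.42 and Inpp5d at 17.7 ± 5.41 against 9.09 ± 2.75 (SD, n = 5 and 3).

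Camera called these 5 lists with its preset correlation (adjusted p = 3.83e-11, 1.26e-07, 4.10e-11, 3.01e-07 and 1.61e-06 in the order given). None held with an estimated correlation (adjusted p = 0.240, 0.258, 0.240, 0.313 and 0.240). Adjusted over the list alone, 14 genes of resting microglia, 8 pathology-associated microglial genes, 15 reactive astrocyte genes (14 higher and 1 lower), 1 interferon gene and 1 signalling gene passed, and over all genes tested none did. In the resting, pathology-associated, reactive astrocyte and interferon lists, 4 of 5 R47H-TREM2 libraries scored above all 3 controls. Their score differences within the libraries low in liver transcripts (3 against 1) were 0.97, 1.71, 2.05 and 1.80, and within the high ones (2 against 2) 0.63, 0.39, 0.54 and 0.57.

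Other groups of this comparison moved too. Myelin genes were higher in 21 of 21 cases (median 0.73; adjusted p = 0.258 with an estimated correlation), with Opalin, an oligodendrocyte membrane protein, at 54.1 ± 15.9 against 20 ± 10.5 CPM (SD, n = 5 and 3). Ependymal genes were higher in 13 of 13 (median 1.24; adjusted p = 0.258 with an estimated correlation; 8 passed when adjusted over the list alone), complement genes in 16 of 19 (median 0.92; 0.244), astrocyte markers in 17 of 19 (median 0.45; 0.258) and antigen presentation genes in 20 of 20 (median 1.14; 0.308). Choroid plexus genes were higher in 20 of 20 (median 1.90; 0.316), a call that ended without the doubted libraries (median 0.88, limma camera adjusted p = 0.412), where only 1 control was left. Genes of striatal projection neurons were lower in 16 of 16 (median −1.24; 0.258), with the dopamine receptor Drd2 at 1.54 ± 0.322 against 8.10 ± 8.63 (SD, n = 5 and 3), the control mean resting on Trem2+/+ female 3 (18.1). Inhibitory neuron markers were lower in 18 of 20 (median −0.39; 0.240), excitatory neuron markers in 14 of 17 (median −0.48; 0.277), genes of CA1 pyramidal cells in 14 of 14 (median −0.31; 0.277), synaptic genes in 30 of 34 (median −0.31; 0.277) and clock genes in 16 of 18 (median −0.40; 0.240). Meningeal genes were higher in 17 of 19 (median 0.87; 0.258), pericyte and smooth muscle genes in 13 of 15 (median 0.46; 0.258), endothelial genes in 16 of 19 (median 0.25; 0.345) and ribosomal protein genes in 58 of 60 (median 0.59; 0.345). Genes of peripheral immune cells were higher in 13 of 17 (median 1.48; 0.258), with 4 of 5 R47H-TREM2 libraries above all 3 controls, and inflammatory cytokine genes in 25 of 30 (median 0.83; 0.258). Without the doubted libraries the peripheral immune call ended at 1.28 (limma camera adjusted p = 0.178). Genes of PI3K, AKT and mTOR signalling, which the series title names, were not called (14 of 39 higher, median −0.13, camera adjusted p = 0.201).

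Single libraries stood behind several of these medians. Without Trem2+/+ female 3, whose striatal score was 2.07, striatal genes stood at −0.50, excitatory neuron markers at −0.14, meningeal genes at 0.37 and ribosomal protein genes at 0.29, and the excitatory and meningeal calls ended. Without Trem2+/+ female 1 myelin genes stood at 0.42, synaptic genes at −0.49 and ribosomal protein genes at 1.13. Without Trem2+/+ female 2 interferon genes stood at 0.75, meningeal genes at 1.34 and ribosomal protein genes at 0.37. R47H-TREM2 female 1 was low in excitatory neuron, CA1 and synaptic genes (scores −1.18, −1.03 and −0.68), and without it meningeal genes stood at 0.57 and astrocyte markers at 0.28. Choroid plexus genes stood at 1.09 without R47H-TREM2 female 2 and interferon genes at 0.79 without R47H-TREM2 female 5. Without the doubted libraries, against 1 control, interferon genes stood at 1.87, complement genes at 1.74, striatal genes at −0.79 and inhibitory neuron markers at −0.14. In the same fit meningeal (0.41), excitatory neuron (−0.26) and endothelial genes (0.06) lost their calls, and camera's direction turned for the meningeal list. The endothelial call also ended in 6 other fits. With the transcript length covariate ribosomal protein genes stood at 0.20, excitatory neuron markers at −0.30 and synaptic genes at −0.15. Camera's direction for the respiratory chain list turned in that fit. Camera also called lipid efflux, unfolded protein and long nuclear RNA lists as higher, and none held with an estimated correlation. In the lipid efflux and unfolded protein lists all 5 R47H-TREM2 libraries scored above all 3 controls, and in the inhibitory neuron list all 5 scored below. These were the only 3 lists at the smallest possible exact permutation p (0.0357, unadjusted), and none passed after adjustment. Camera further called lysosomal (median 0.32), heat shock (0.17) and respiratory chain genes (0.31) as higher. Cholesterol synthesis (−0.35), cortical (−0.39) and glucocorticoid genes (−0.68) were called as lower. Each of these calls ended without 1 library, and none held with an estimated correlation. Without R47H-TREM2 female 2 lysosomal genes stood at 0.16 and cortical genes at −0.27, without Trem2+/+ female 1 heat shock genes at 0.05 and glucocorticoid genes at −0.18, without Trem2+/+ female 2 cholesterol synthesis genes at −0.17, and without Trem2+/+ female 3 respiratory chain genes at 0.05.

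In all, camera called 23 lists as higher and 9 as lower of 41 in this comparison, and 0 with an estimated correlation, by fry or by exact permutation of list scores (smallest adjusted p = 0.240, 0.0613 and 0.209). An unadjusted exact permutation p could not go below 0.0357 here, so a single list could not pass after adjustment. Adjusted over the list alone, 90 list entries passed. Without the doubted libraries, with 4 libraries against 1 control, camera called 19 as higher and 8 as lower. No single gene passed in edgeR's quasi-likelihood test (0 of 16118, smallest adjusted p = 0.140), while 2262 genes had an unadjusted p under 0.05. Uniform p-values would give 805.9, but other groupings of the 8 libraries gave a median of 1091 and up to 3793. Of 56 groupings, 11 gave as many as the real one or more, the real one included. DESeq2 called 147 genes higher and 40 lower, and limma-voom called 0. The smallest edgeR p-values belonged to Omp, Sdf2l1, Wdr6, Ddo, Hist1h2be, Kcna5, Pdpn, Pbxip1, S100a5 and Agtrap. Wdr6 measured 117 ± 9.71 CPM against 212 ± 5.15 (SD, n = 5 and 3; log2 fold change −0.86, SE 0.18, adjusted p = 0.140), and Pdpn, a glial and lymphatic membrane glycoprotein, 48.6 ± 20.3 against 18.1 ± 4.90 (1.43, SE 0.31, adjusted p = 0.141). Omp and S100a5, both of olfactory sensory neurons, were high in Trem2+/+ female 1 alone (419 and 119 CPM). Leaving out R47H-TREM2 female 4 gave 7 calls in edgeR, including Sdf2l1 and Pdpn, and leaving out Trem2+/+ female 2 or 3 gave 1 (Omp) and 2 (Omp and Cdhr1).

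**Figure D3:**
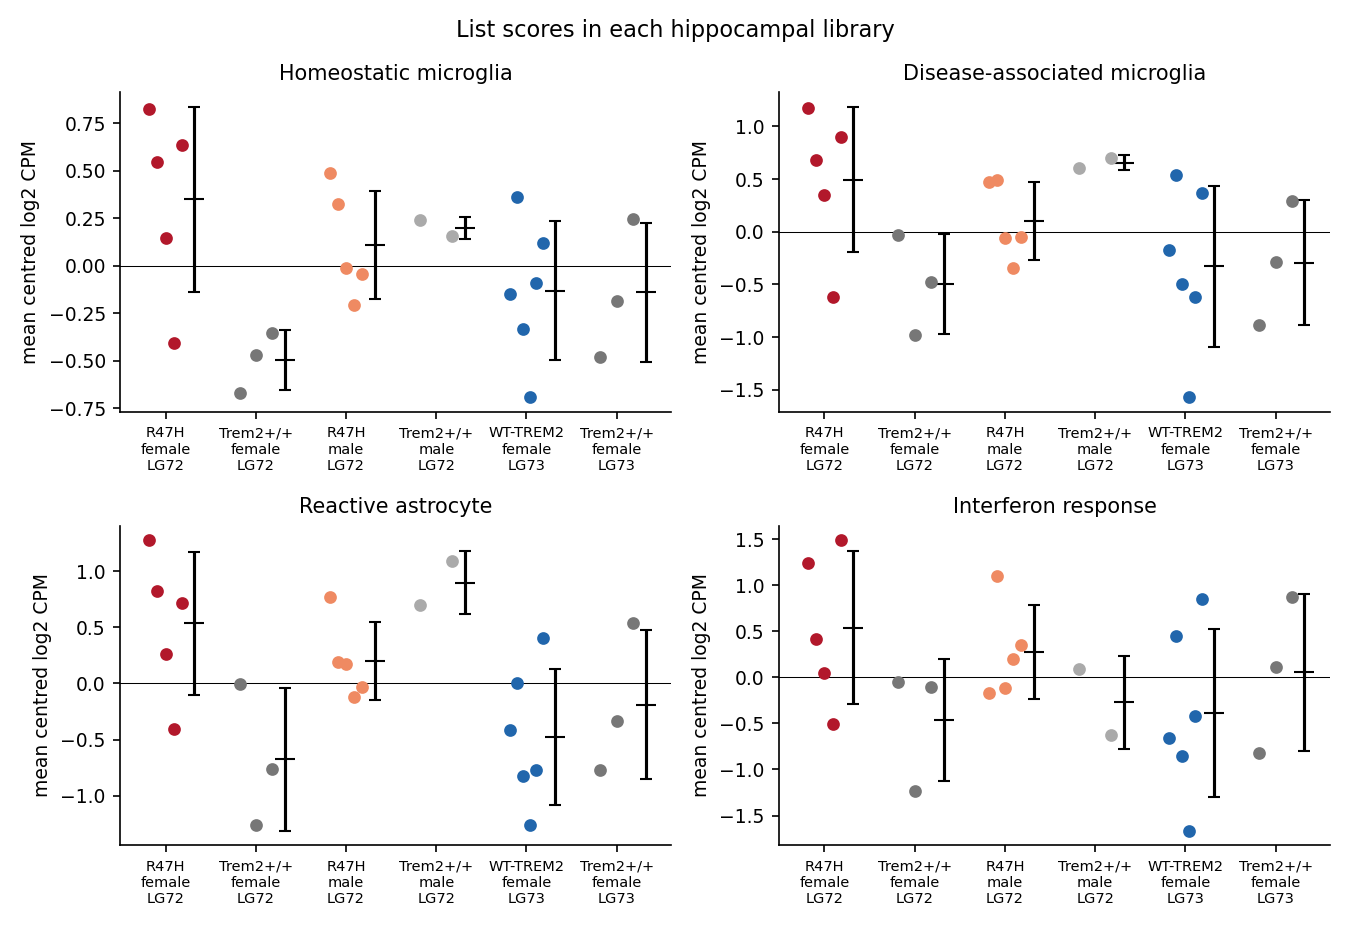
Score of 4 gene lists in each library (mean log2 expression relative to the mean over all 24 libraries), with points for libraries and bars for the group mean and SD. In R47H-TREM2 females of LG72, 4 of 5 libraries lie above all 3 controls for the resting microglia list, and the fifth is library 4.

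The second comparison asked the same of R47H-TREM2 and Trem2+/+ males of LG72, 5 against 2. Nuclear genes of the respiratory chain were higher in 39 of 41 cases (median log2 fold change 0.69) and ribosomal protein genes in 60 of 60 (median 0.75; adjusted p = 0.594 for both with an estimated correlation). With each library's trend of expression with transcript length as a covariate these medians were 0.22 and 0.15, the control male 2 having the steepest slope of the males (0.140). Atp5k, an ATP synthase subunit, measured 156 ± 72.3 CPM against 68.2 ± 10.4 and Rps16 33.1 ± 18.6 against 9.27 ± 0.00711 (SD, n = 5 and 2). Choroid plexus genes were higher in 20 of 20 cases (median 2.59; 0.648), with the thyroid hormone carrier Ttr at 990 ± 995 against 85.2 ± 35.2 (SD, n = 5 and 2). The rise was not shared by all libraries: R47H-TREM2 males 1 to 5 scored 1.14, −1.94, −1.33, 2.52 and 2.32, and the 2 controls −0.88 and −1.45. Pathology-associated microglial genes were lower in 30 of 35 (median −0.40), reactive astrocyte genes in 23 of 29 (median −0.66) and inflammatory cytokine genes in 20 of 30 (median −0.67; 0.594 for these 3). Gpnmb, a microglial glycoprotein, measured 6.15 ± 3.31 against 30.5 ± 23.3 (SD, n = 5 and 2; log2 fold change −2.31, SE 0.73, edgeR adjusted p = 0.779). Resting microglia genes were not called (11 of 26 higher, median −0.12). Interferon-stimulated genes were higher in 30 of 34 (median 0.60; 0.752), at 1.23 without Trem2+/+ male 1, and the call ended without Trem2+/+ male 2 (0.37), without R47H-TREM2 male 2 (0.26) and with the length covariate (0.36). Without Trem2+/+ male 2, and so with 1 control, respiratory chain genes stood at 0.40, pathology-associated microglial genes at −0.26, reactive astrocyte genes at −0.34 and inflammatory cytokine genes at −0.21. Without R47H-TREM2 male 4 ribosomal protein genes stood at 0.42 and inflammatory cytokine genes at −0.44.

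Genes raised by glucocorticoids were lower in 19 of 19 cases (median −0.82; adjusted p = 0.594 with an estimated correlation), and 10 passed when adjusted over the list alone. The fall rested on Trem2+/+ male 2: without it, and so with 1 control, the median was 0.01 and the call ended. Clock genes (median −0.15) and genes of PI3K, AKT and mTOR signalling (30 of 39 lower, median −0.24; both 0.594 with an estimated correlation) went the same way, to −0.03 and 0.02. Without Trem2+/+ male 1 the 3 lists stood at −1.37, −0.38 and −0.43, and with the length covariate clock genes stood at −0.25 and the PI3K, AKT and mTOR call ended at −0.08. The smallest p-values were those of Cyr61, Zfp36, Cdkn1a, Mfsd2a, Smad1, Csrnp1, Maff, Apold1, Rtp1 and Slc38a2, all lower in R47H-TREM2 males. Cdkn1a, a cell cycle inhibitor, measured 13.7 ± 2.83 CPM in 5 R47H-TREM2 males and 21.1 and 152 in the 2 controls, and Cyr61, a matrix-associated protein, 4.98 ± 2.02 against 7.44 and 174 (SD, n = 5). Camera called 7 lists as higher and 12 as lower, and 0 with an estimated correlation, by fry or by permutation (smallest adjusted p = 0.594, 0.677 and 0.689), where an exact permutation p could not go below 0.0952. The called lists not described above were complement, TREM2 signalling, lysosomal, CA3 and CA2, synaptic and immediate early genes (lower) and cholesterol synthesis, myelin and ependymal genes (higher), and of these all but the lysosomal list lost the call without Trem2+/+ male 1 or without Trem2+/+ male 2. In males 15 list entries passed when adjusted over the list alone. In edgeR 0 genes passed (smallest adjusted p = 0.164; 995 genes at an unadjusted p under 0.05), in limma-voom 0 and in DESeq2 3 (Cdkn1a, Zfp36 and Cyr61, lower). Without Trem2+/+ male 1 edgeR called 48 genes, 16 higher and 32 lower, with 1 control left and the spread taken from the other groups. Within libraries low in liver transcripts (1 against 1) and high in them (4 against 1), score differences were 0.66 and 0.47 for the respiratory chain, 0.52 and 0.54 for ribosomal proteins, and −1.57 and −0.01 for glucocorticoid genes.

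The third comparison set WT-TREM2 against Trem2+/+ females of LG73, as the control for the human allele. Choroid plexus genes were lower in 20 of 20 cases (median log2 fold change −2.15; adjusted p = 0.828 with an estimated correlation). Kl, the choroid plexus protein klotho, measured 25 ± 16.4 CPM against 94.2 ± 37.5 and Steap1 1.17 ± 1.19 against 7.52 ± 4.52 (SD, n = 6 and 3; log2 fold changes −1.92 and −2.69, SE 0.60 and 0.86, edgeR adjusted p = 0.860 for both). Ependymal genes were lower in 13 of 13 (median −0.76; 0.828), and all 6 WT-TREM2 libraries scored below all 3 controls. Genes of striatal projection neurons were higher in 15 of 16 (median 1.11; 0.934), and without the doubted libraries the median was −0.03. Without WT-TREM2 female 2 it was 0.53, and with the transcript length covariate 0.45. Interferon-stimulated genes were lower in 27 of 34 (median −0.35, camera adjusted p = 0.00487; 0.963). That call ended without Trem2+/+ female 3 (0.17), without WT-TREM2 female 1 (−0.35), 3 (−0.35) or 4 (−0.24) and without the doubted libraries (0.08). The median was −0.64 without Trem2+/+ female 1, −0.62 without WT-TREM2 female 6, −0.57 with a surrogate variable or the liver split and −0.66 with the length covariate. Genes of dentate granule cells were lower in 17 of 19 (median −0.34, camera adjusted p = 0.00181; 0.934). That call ended without Trem2+/+ female 2 (−0.02) and with the length covariate (−0.17), and the median was −0.53 without Trem2+/+ female 3 and −0.18 with a surrogate variable. Lists of resting and pathology-associated microglia were not called (medians 0.11 and 0.10, camera adjusted p = 0.835 and 0.949), nor were reactive astrocytes (median −0.25, 0.0615) or PI3K, AKT and mTOR signalling (median −0.13, 0.0629).

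Camera called 5 lists as higher and 8 as lower in WT-TREM2 females, and 0 with an estimated correlation, by fry or by permutation (smallest adjusted p = 0.828, 0.960 and 0.976). The unadjusted exact permutation p was 0.0476 for choroid plexus and 0.0238, the smallest possible, for ependymal scores. With that floor a single list could not pass after adjustment. The called lists not described above were synaptic, immediate early, meningeal and thalamic genes (lower) and cortical genes and long nuclear RNA (higher). Each lost its call without some single library, among them Trem2+/+ female 2 for synaptic (−0.04), immediate early (0.00) and thalamic genes (−0.15), WT-TREM2 female 5 for meningeal genes (−0.19), and Trem2+/+ female 3 for cortical genes (0.35) and Trem2+/+ female 1 for long nuclear RNA (0.55). Adjusted over the list alone, 18 list entries passed, all of them choroid plexus genes. Within libraries low in liver transcripts (2 against 2) and high in them (4 against 1), choroid plexus scores differed by −0.93 and −3.53 and ependymal scores by −0.85 and −0.93. Ribosomal protein genes (55 of 60 higher, median 0.42) and respiratory chain genes (38 of 41 higher, median 0.37; 0.963 for both with an estimated correlation) lost their calls without the doubted libraries (medians 0.12 and 0.04) and with a surrogate variable (0.10 and 0.04), and stood at 0.19 and 0.17 with the liver split as a term. Without WT-TREM2 female 2 the respiratory chain call ended at 0.22. With each library's trend of expression with transcript length as a covariate their calls turned to lower (medians −0.07 and −0.08). In edgeR 0 genes passed (smallest adjusted p = 0.860; 630 genes at an unadjusted p under 0.05), and 0 in DESeq2 and limma-voom. The smallest p-values were those of Adck4, Rexo4, Hbegf, Srl, Rbm15, Slc12a1, Ldhd, Ttc4, Rrnad1 and Hrh3. Hbegf, a growth factor, measured 21.6 ± 10.9 against 9.13 ± 0.265 (SD, n = 6 and 3; log2 fold change 1.24, SE 0.32, adjusted p = 0.860).

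**Figure D4:**
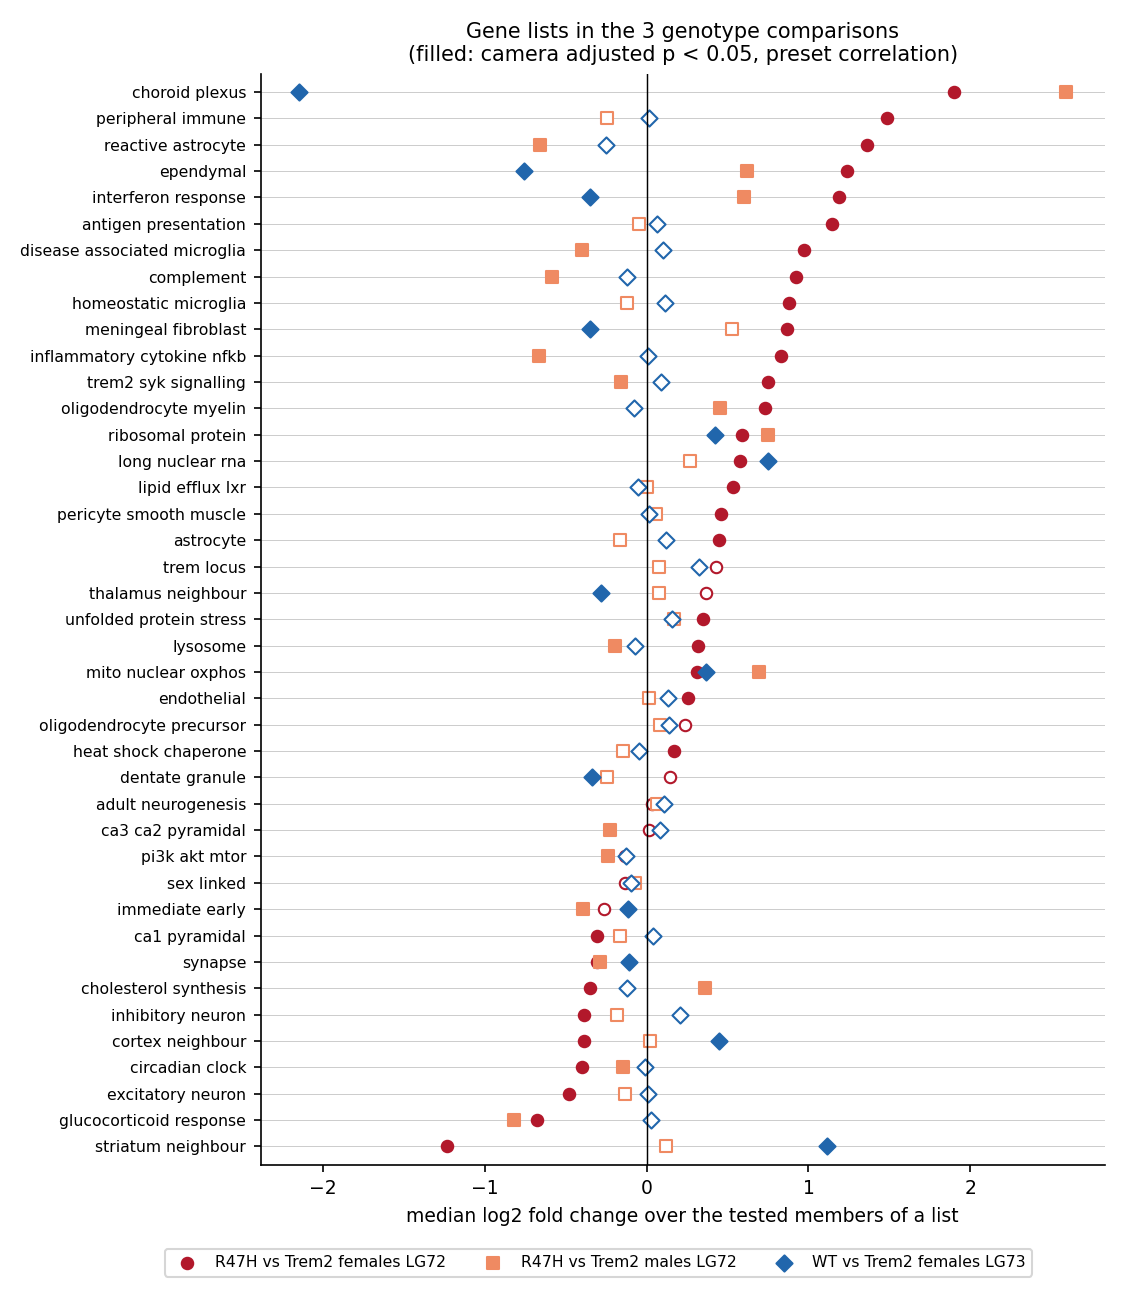
Median log2 fold change of each of 41 gene lists in the 3 genotype comparisons, filled where camera with its preset correlation gave an adjusted p under 0.05. Resting microglia stand at 0.88 in R47H-TREM2 females, −0.12 in R47H-TREM2 males and 0.11 in WT-TREM2 females, and choroid plexus at 1.90, 2.59 and −2.15. For choroid plexus 3 of 5 R47H-TREM2 males scored above both controls and 1 below both.

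The R47H effect was set against the WT effect in females as a difference of the differences from the Trem2+/+ libraries of each prefix. Choroid plexus (median difference 4.16, 20 of 20 genes higher), ependymal (1.95, 13 of 13), reactive astrocyte (1.54, 28 of 29), interferon (1.41, 33 of 34), pathology-associated microglial (0.89, 28 of 35) and resting microglial genes (0.87, 24 of 26) had a higher effect with R47H-TREM2. The interferon list had a median of 1.19 in the R47H comparison and −0.35 in the WT comparison. Striatal genes had a lower one (−2.43, 16 of 16 lower), with high scores only in the doubted libraries Trem2+/+ female 3 of LG72 (2.07) and WT-TREM2 females 2 and 5 (1.88 and 1.49) and none above 0.47 elsewhere. With an estimated correlation the adjusted p was 0.211, 0.211, 0.211, 0.309, 0.360, 0.224 and 0.211 in this order. The gap between Trem2+/+ females of the 2 prefixes entered these differences. Their choroid plexus scores were −0.80, 0.49 and −2.04 in LG72 and 1.93, 1.60 and 0.16 in LG73. Their ependymal scores were −0.37, −0.99 and −0.80 against 0.56, 0.43 and 0.50. For these 2 lists the higher effect therefore does not rest on the human-allele libraries alone. Camera called 20 lists as higher and 8 as lower, and 0 with an estimated correlation, by fry or by permutation (smallest adjusted p = 0.211, 0.130 and 0.0639). Adjusted over the list alone, 56 list entries passed, among them 20 choroid plexus genes. In edgeR 0 genes passed (smallest adjusted p = 0.244; 1459 genes at an unadjusted p under 0.05), in limma-voom 0 and in DESeq2 13. The 13 were Dab2, Gbp2, Pdpn, Pm20d1 and Tgfbi with a higher effect and Adora2a, Drd2, Hap1, Hrh3, Htr1d, Kcnt1, Nlrp6 and Rxrg with a lower one, of which Adora2a, Drd2 and Rxrg are on the striatal list.

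The R47H effect was compared between the sexes, where lists were called only by camera with its preset correlation. Reactive astrocyte (median difference 1.86, 29 of 29 genes higher in females), pathology-associated microglial (1.31, 33 of 35), resting microglial (0.91, 26 of 26), complement (1.35, 17 of 19), TREM2 signalling (1.12, 20 of 21) and inflammatory cytokine genes (1.05, 25 of 30) had a higher effect in females. Cholesterol synthesis genes had a lower one (−0.68, 23 of 24 lower). With an estimated correlation the adjusted p was 0.122, 0.136, 0.140, 0.133, 0.133, 0.133 and 0.180 in this order. The gap between the controls of the 2 sexes entered these differences. Pathology-associated microglial scores were −0.03, −0.97 and −0.47 in the 3 Trem2+/+ females and 0.61 and 0.70 in the 2 Trem2+/+ males. Of these females 2 were doubted libraries. R47H-TREM2 scores overlapped, at 1.17, 0.68, 0.35, −0.62 and 0.89 in females and 0.47, 0.49, −0.05, −0.35 and −0.05 in males. Camera called 19 lists as higher and 6 as lower, and 0 with an estimated correlation, by fry or by permutation (smallest adjusted p = 0.122, 0.127 and 0.126). For the difference between the sexes 41 list entries passed when adjusted over the list alone. In edgeR 0 genes passed (smallest adjusted p = 0.696; 860 genes at an unadjusted p under 0.05), in limma-voom 0 and in DESeq2 1 (Calb2, a calcium-binding protein of interneurons, with a lower effect in females).

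Male and female R47H-TREM2 libraries of LG72 differed in genes of the sex chromosomes. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were higher in males, and Xist, the RNA that silences an X chromosome, was lower. Xist measured 0.623 ± 0.461 CPM in males and 229 ± 91.6 in females, and Ddx3y 58.1 ± 7.89 and 0.126 ± 0.189 (SD, n = 5 and 5; log2 fold changes −8.49 and 8.84, SE 0.59 and 0.55, edgeR adjusted p = 9.59e-10 and 2.57e-10). EdgeR called 4 genes higher and 1 lower, DESeq2 7 and 3, and limma-voom 7 in all. Trem2+/+ females of LG72 and LG73, 3 against 3, had 0 genes past the threshold in edgeR (smallest adjusted p = 0.771; 691 genes at an unadjusted p under 0.05), 0 in limma-voom and 2 in DESeq2 (Vip, a neuropeptide, and Cdkn1a, higher in LG72). Camera with its preset correlation called 19 lists between these 2 groups of the same genotype, against 13 for WT-TREM2 females, and 11 to 24 in the 9 other ways to part the 6 libraries into 3 and 3.

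Fold changes of the 3 genotype comparisons, which share no library, were correlated across 16118 genes, which are not independent replicates. Those of R47H-TREM2 females and R47H-TREM2 males had a Spearman correlation of 0.285 (Pearson 0.231), those of R47H-TREM2 and WT-TREM2 females 0.0528 (−0.125), and those of WT-TREM2 females and R47H-TREM2 males 0.317 (0.0783). The last fell to 0.0585 with the transcript length trend as a covariate.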

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

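The patterns weighed here and their tests were chosen after the results were seen, apart from the counts under regrouped libraries, whose rule was written first (the DESeq2 count was seen before its regrouping was chosen).

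In R47H-TREM2 females of LG72 the lists of resting and pathology-associated microglia, reactive astrocytes and interferon genes were higher, with a median of 1.08 over their genes. A lower share of neurons could raise them, but the 4 lists exceeded the endothelial list by 0.848 (SE 0.448), which left this undecided, and pericyte genes were higher too (0.46). With the liver split as a term the median was 1.06 (SE of the fall 0.130), so a shift shared by all groups is unlikely to account for it. The term could not capture a shift that differed between groups. Score differences of the 4 lists were 0.63, 0.39, 0.54 and 0.57 within the high libraries (2 against 2). Within the low ones (3 against 1) they were 0.97, 1.71, 2.05 and 1.80. Thinned to the smallest total the median was 1.10 (SE of the fall 0.0790), but thinning leaves expected ratios as they are. All 5 R47H-TREM2 libraries were shallower than all 3 controls, so depth and genotype cannot be told apart. Of 56 groupings of the 8 libraries, 5 gave a mean score as far from 0 (real 1.01, highest other −1.27), so chance is not excluded.

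Ribosomal protein and respiratory chain genes were higher in the human-allele libraries of all 3 genotype comparisons, with a mean of the 6 medians of 0.521. With the transcript length slope of other genes as a covariate the mean was 0.0668 (SE of the fall 0.217), so a trend with transcript length, as from RNA quality or library preparation, may account for most of it. Thinning to the smallest total left 0.505 (SE of the fall 0.0568), which leaves depth open, since thinning does not change expected ratios. Of 98784 combined regroupings 3473 were as far from 0 (real 0.478, highest other 0.826), but the 2 lists were chosen among 41 for this same pattern, so this excludes nothing.

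The rule that decided the liver, depth and length tests was changed after the results were seen. The first rule used the SE of the remaining value itself and left 3 tests undecided: liver batch (1.06, SE 0.436), depth for the glial lists (1.10, SE 0.354) and depth for the ribosomal and respiratory chain lists (0.505, SE 0.267). The second rule used the SE of the fall and excluded those 3 causes, but depth was then left open in both patterns, since thinning cannot test it. The length test came out the same under both (0.0668, SE 0.130). The exclusion of liver batch, which covers only a shift shared by all groups, therefore carries less weight than if the rule had been kept.

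Liver transcripts stood high in 14 of 24 libraries. Of 20 liver genes 18 were higher in each of the 14 than in any other library, which may point to carry-over of liver RNA or reads. Alb, by which the 14 were split, is among these 18, so its part was fixed beforehand. A single carry-over of liver and heart in a fixed mix is unlikely, since in 3 of the 14 (Trem2+/+ female 3 of LG72, R47H-TREM2 male 5 and Trem2+/+ female 1 of LG73) the heart sum did not pass the highest of the other libraries (7.21 CPM).

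Under regrouped libraries the counts of R47H-TREM2 females were as large in 56 of 56 groupings for genes at an adjusted p under 0.05 (real 0, highest other 234), which a real count of 0 fixes and which tells nothing of chance. They were as large in 11 of 56 at an unadjusted p under 0.05 (2262, 3793). For lists called by camera it was 1 of 56 (32, 30), and for DESeq2 12 of 56 (187, 1128). Only the list count met the rule written first for excluding chance. It was 1 of several counts tried without correction, and 1 of 56 is the least this test can give. Camera called a median of 14 lists in the other groupings, so this is weak evidence against chance. Other groupings calling several times the real count may reflect a structure of the samples, which was not tested. For WT-TREM2 females the numbers were 84 of 84 (0, 1), again fixed, and 27 of 84 (630, 4239) and 46 of 84 (13, 27), where chance is not excluded.

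For the difference of the R47H and WT effects they were 100 of 100 (0, 2110), fixed as well, and 19 of 100 (1459, 4890) and 5 of 100 (28, 29), where chance is not excluded. For males against females the rule for excluding chance was met for adjusted calls, 2 of 100 (5, 27), and not for unadjusted ones, 22 of 100 (1134, 3059). For Trem2+/+ females of the 2 prefixes there were too few groupings to tell: 10 of 10 (0, 0) and 4 of 10 (691, 1397).

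In 8 of 138 groups a library stood far from the others by Dixon's test, which chance does in about 1 in 20 groups (6.9 here). R47H-TREM2 female 1 was low in excitatory neuron (−1.18) and synaptic genes (−0.68). R47H-TREM2 male 4 was low in Prnp (log2 CPM 10.41) and inhibitory neuron genes (−0.41) and high in long nuclear RNA (0.71), and R47H-TREM2 male 1 was low in clock genes (−0.24). WT-TREM2 female 2 was low in genes of PI3K, AKT and mTOR signalling (−0.45) and WT-TREM2 female 3 in long nuclear RNA (−0.48).

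Of 82 list scores tested for a difference between 2 effects, 16 had an unadjusted exact permutation p under 0.05, and none passed after adjustment. Between the R47H and WT effects these were choroid plexus (4.05, exact permutation p = 0.00468), ependymal (1.97, p = 0.00425), inhibitory neuron (−0.56, p = 0.00298), striatal (−1.89, p = 0.0132), cortical (−0.89, p = 0.0272) and reactive astrocyte scores (1.499, p = 0.0438). The striatal score was high only in the doubted libraries Trem2+/+ female 3 of LG72 (2.07) and WT-TREM2 females 2 and 5 (1.88 and 1.49). The choroid plexus and ependymal differences include a gap between the Trem2+/+ females of the 2 prefixes.

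Between the R47H effects in females and males they were complement (1.22, exact permutation p = 0.00510), reactive astrocyte (1.91, p = 0.00680), TREM2 signalling (0.99, p = 0.0119), inflammatory cytokine (1.27, p = 0.0136), pathology-associated microglial (1.54, p = 0.0153), peripheral immune (1.03, p = 0.0187), lysosomal (0.56, p = 0.0255), striatal (−1.30, p = 0.0323), astrocyte (0.68, p = 0.0442) and resting microglial scores (0.93, p = 0.0459). Among these libraries the striatal score was high only in the doubted Trem2+/+ female 3 (2.07). All of these differences include the gap between the Trem2+/+ libraries of the 2 sexes.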

How the results depend on the processing

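The liver split, the transcript length covariate, the set without doubted libraries and the exact permutation of list scores were chosen after results were seen. No paired analysis was possible because replicate numbers follow the order of accessions and pair no libraries.

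Taken per comparison and setting, 16 counts of genes at an adjusted p under 0.05 moved from 0 or by over 1.5 times. DESeq2 called 187 genes in R47H-TREM2 females, 3 in R47H-TREM2 males, 13 for the difference of the R47H and WT effects, 1 for the difference between the sexes, 10 for males against females and 2 between prefixes. In R47H-TREM2 females edgeR called 1 gene (Omp) with no filter and 1 (Omp) with the length covariate, and the direct contrast of R47H-TREM2 with WT-TREM2 called 1 (Hap1). Leaving out single libraries gave 0 to 7 calls in R47H-TREM2 females (7 without R47H-TREM2 female 4), 0 to 48 in R47H-TREM2 males (48 without Trem2+/+ male 1, which leaves 1 control), 0 to 1 for each difference of effects and 0 to 2 between prefixes. The cause was not tested.

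Camera's calls of lists ended in all 5 comparisons, with 0 called with an estimated correlation, 0 by fry and 0 by exact permutation. An exact permutation p could not go below 0.0357 in R47H-TREM2 females, 0.0238 in WT-TREM2 females and 0.0952 in R47H-TREM2 males. A single list could therefore not pass there after adjustment, so these 0 calls by permutation say little. Leaving out single libraries gave 12 to 20 lists in R47H-TREM2 males (12 without Trem2+/+ male 2, against 1 control). Of single lists, 668 values kept their call and direction, 274 lost the call and 12 turned in camera's direction, which is set against all other genes, so that a median may keep its sign. Without the doubted libraries these were meningeal (0.41) and glucocorticoid genes (−0.0913) in R47H-TREM2 females (1 control left) and striatal (−0.0322) and respiratory chain genes (0.0450) in WT-TREM2 females. With the length covariate they were respiratory chain genes in R47H-TREM2 females (−0.0676) and synaptic (0.00891), ribosomal (−0.0670) and respiratory chain genes (−0.0824) in WT-TREM2 females. Over single libraries left out, glucocorticoid genes ran from −0.94 to −0.18 in R47H-TREM2 females and from −1.37 to 0.0128 in males, and in males PI3K, AKT and mTOR genes from −0.43 to 0.0241 and clock genes from −0.38 to −0.0251. The cause was not tested.

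The correlation of fold changes between WT-TREM2 females and R47H-TREM2 males was 0.0585 with the length covariate. Named genes turned in 29 values and kept their direction in all others. Mfsd2a stood at 0.00403 in R47H-TREM2 females without the doubted libraries, against 1 control. Foxp2 stood at −0.22 in WT-TREM2 females with pooled controls. Prnp in WT-TREM2 females stood at 0.12 with a surrogate variable, 0.10 with the liver split, 0.0725 with the length covariate and 0.00195 without the doubted libraries, and ran from −0.10 to 0.0731 over single libraries left out. Mapt ran from −0.14 to 0.21 in R47H-TREM2 females. In R47H-TREM2 males Apold1 ran from −2.95 to 0.50, Ddit4 from −1.37 to 0.19, Fbln5 from −2.45 to 0.0375 and Grin2a from −2.001 to 0.41. The cause was not tested.

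Trem2 stood at −0.26 in R47H-TREM2 females with the length covariate and ran from −0.31 to 0.60 over single libraries left out. In WT-TREM2 females Trem2 stood at −0.26 with limma-voom, −0.25 with a surrogate variable, −0.19 with pooled controls, −0.15 with the liver split, −0.78 with the length covariate and −0.18 without the doubted libraries, and ran from −0.51 to 0.47. As a difference of mean log2 values Trem2 ran from −0.41 to 0.68 in R47H-TREM2 females and from −0.68 to 0.0374 in WT-TREM2 females. The cause was not tested.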

Other observations

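The 2 hypotheses below and their tests were chosen after results were seen.

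Trem2 was set against the resting microglia list, on the untested premise that its level follows the share of microglia. Log2 Trem2 less the resting microglia score was lower with a human allele by −0.653 on average over the 3 genotype comparisons (combined permutation p = 0.0308). It was −0.63 in R47H-TREM2 females, −0.31 in WT-TREM2 females and −1.02 in R47H-TREM2 males (exact permutation p = 0.321, 0.619 and 0.0952). Without the scaling the mean was −0.397 (combined permutation p = 0.295). This might reflect the replacement of 1 mouse Trem2 allele in these mice, and the choice of the scaling decided it.

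Treml1, a platelet receptor gene next to Trem2, had 4 to 51 counts in each of 6 WT-TREM2 females and 10 in all of their 3 controls, 9 of them in 1 library, 20 in 5 R47H-TREM2 females, 16 of them in 1 library and none in 3, and 7 in their 3 controls, and 0 in all males. The exact permutation p was 0.0714 in LG73 females and 1 in LG72 females, so higher transcription of the locus with the human allele could be neither shown nor excluded.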
